A study of Oncorhynchus tshawytscha and Oncorhynchus mykiss with 197 samples.

How the data were processed

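Liver RNA of juvenile chinook salmon (Oncorhynchus tshawytscha) was measured on 197 cDNA microarrays from 2 exposure experiments run in consecutive years. In each experiment fish were held in seawater or in untreated municipal sewage diluted with seawater. The concentrations were 0.05%, 0.1%, 0.7% and 2% in both years, with a highest concentration of 10% in year 1 or 5% in year 2. Livers were sampled after 1, 4 and 8 days of exposure, and on day 16, after 8 further days in clean seawater. Groups were taken from the sample titles, which gave 48 groups, 6 for each of the 8 combinations of year and day. A group held 4 arrays, apart from 8 for the control of year 1 day 4, 3 at 2% on year 1 day 4, and 5 at 0.05% and at 2% on year 1 day 8. The labels do not say that each array came from a separate fish, so p-values measure only the spread between these samples, which may be partly technical.

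Per the labels' protocols, RNA came from a 30 mg piece of liver and 25 ug of it carried the Cy5 dye, while a universal DNA reference made from rainbow trout material was labelled with Cy3 and hybridised to the same array. No dyes were swapped, so each ratio runs from liver cDNA over the common reference, and a dye effect of a probe is shared by the groups and drops out of their difference. The deposited file of each array gives, per the file headers, the mean spot intensity and the mean local background intensity in both channels, with no correction or normalization applied. The scanner and the image software are not given in the sources used here. The authors also deposited a table of log2 values for the 197 arrays with 214 entries that carry no gene names. Its floor of -6.64 and its negative and positive values point to log2 units, but its centring, its direction and the steps behind it stay unknown. The medians of 173 of its columns lay between -1 and 1, and those of the 24 arrays of year 2 day 16 lay between -5.35 and -4.07. It served only as an alternative, each column centred on its median, over the 209 entries without missing values.

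Each array carried 576 spots: 203 gene probes with 2 spots each (4 for PSMB9), 58 blank spots, 80 GFP and 24 Arabidopsis spike spots, and 3 genomic or intron control probes. Gene names are those of the array files. Different probes of 1 gene are kept apart by the number the array files give them, as in CYP3A27 d195, and 2 probes had names with no standard meaning and were kept as given. Background was corrected with normexp and an offset of 50 (limma 3.58.1 under R 4.3.3), the log2 ratio of Cy5 to Cy3 was taken, the spots of a probe were averaged, and each array was centred on the median of its gene probes. All log2 values below are on this scale. Loess within each array, the usual treatment of 2-colour arrays, was an alternative fixed in advance and not the main setting, because the reference is DNA that holds the printed genes in fixed amounts, so the log ratio follows the Cy5 signal by construction.

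A probe was taken as above background on an array when its background-subtracted Cy5 signal exceeded the mean of the blank spots by 2 SD. It was tested at a year and day when it was above background on at least 50% of the arrays of at least 1 group there. Where a probe was not above background on any array of 1 of the groups compared, its fold is given as a lower bound, the brighter group's mean over the mean, per array, of the higher of the lowest signal among probes above background and the probe's own signal. Precision is limited by the number of arrays and by signal. In year 1 the median array had a median Cy5 intensity of 247 over a background of 203, and 65 of the 203 probes above background (range 7 to 91). In year 2 these were 633 over 370 and 191 probes (range 3 to 203).

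For each year and day, limma (lmFit and eBayes with an intensity trend) compared each concentration with the control of the same year and day in 1 fit over the 6 groups, with Benjamini-Hochberg adjustment jointly over the 5 concentrations and all tested probes. The threshold was an adjusted p of 0.05, and tests were two-sided. A second fit gave the slope per step of concentration, ranked from control to highest. The array series is the first number in an array's name. On year 1 day 4 each of the 2 series held 4 controls, so series entered as a fixed term and each concentration was set against controls of its own series. On year 1 day 1 the control arrays lay in another series than every exposed array, and series and exposure cannot be told apart. Differences between years at 2%, and between day 16 and day 8 at the highest concentration, were interaction contrasts in 1 fit over the 48 groups, with adjustment jointly over days or years. A probe entered these when it was kept at both occasions compared. A first version of this filter, probes kept in both years as wholes, is listed among the alternatives.

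Gene lists were fixed by name patterns before the data were examined: biotransformation of foreign chemicals, estrogen-responsive and reproductive genes, metal binding and oxidative defence, heat shock and protein turnover, immune and acute phase, hormone signalling, metabolism, cell cycle and damage, ion and water transport, housekeeping, and markers of red blood cells, of leukocytes, and of muscle or pancreas. Of the 203 probes, 122 fell in at least 1 of the 13 lists, after 9 hits on unrelated names were removed. Lists with at least 3 tested probes were tested at the highest concentration with fry, which asks whether a list's probes move, on balance, one way, adjusted over 81 tests. Camera with a preset and with an estimated correlation was run beside it.

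Named genes followed a rule fixed in advance: up to 8 rises and 8 falls that passed at the highest concentration, up to 3 each way at each lower concentration, the 5 steepest slopes each way, the 5 smallest adjusted p of each difference test, up to 4 members of a list that passed, and the 3 smallest p where nothing passed. Sentinel genes were to be named in any case: CYP1A1, vitellogenin, estrogen receptor alpha, metallothionein, HSP70, the glucocorticoid receptor and the thyroid hormone receptors. No value is given for vitellogenin, the glucocorticoid receptor or the thyroid hormone receptor THRB on any day of year 1. Values of the thyroid hormone receptor THRA on days 1, 4 and 8 of year 1, and of HSPA1A on day 1 of year 1, are also not given. The vitelline envelope rises of year 1 therefore stand without a vitellogenin value. The array held no probe named for pcna. Of the single-gene results, 2 are not reported here; the tests and counts over all probes include them, and no other gene was named in their place.

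The steps were tested on simulated data, with 10 probes shifted by 1 and 10 by 2 on the log2 scale at the highest concentration. At a shift of 1, the concentration test recovered 7, 5, 3 and 3 of 10 on days 1, 4, 8 and 16 of year 1 and 9, 9, 8 and 9 of 10 in year 2. At a shift of 2 it recovered 9 or 10 of 10 everywhere. With no shift it called 0 probes at 7 of the 8 occasions and 1 on year 2 day 8. With the shifts in place, false calls among the other tests numbered 1 on year 1 day 8, and 5, 2 and 3 on days 1, 4 and 8 of year 2, and 0 elsewhere. The noise was drawn independently for each probe and array, in 1 draw, without array-wide or series effects. False calls in the real arrays may therefore be more frequent. Alternatives covered normalization, background, filter, array series, replicate number, model, adjustment and leaving out each array in turn. GFP centring took the median log2 Cy5 signal of the GFP spots, not their log ratio, off the log ratios of each array. Differences between arrays in Cy3 therefore stay in it, and the median Cy3 intensity of arrays ran from 1730 to 7300 in year 1. No 2 arrays were identical, and no genome was used here.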

Results

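Hepatic transcript levels of juvenile chinook salmon were compared between seawater controls and fish held in diluted untreated sewage, to ask which liver genes respond, at which concentration and after how long, and whether a response is still seen after the fish return to clean water. The liver answers to several classes of compound that sewage can carry: estrogens act on genes of egg formation, and aromatic pollutants on the cytochrome P450 genes. The array held 203 probes for genes of reproduction, biotransformation, immunity, stress, hormone signalling, metabolism and transport. Each of the 197 arrays set liver cDNA against a common reference, and whether each came from a separate fish is not stated. Year 1 arrays were dim: between 70 and 85 probes could be tested on a given day, against 179 to 203 in year 2. Differences are log2 of sewage over control with their standard error (SE), and p is limma's, adjusted by Benjamini-Hochberg. Levels are log2 ratios to the reference, centred on each array's median, with SD over arrays. A gene is said to rise or fall only where that p was under 0.05.

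On day 4 of year 1, the 3 vitelline envelope genes rose together at 10% sewage. They encode eggshell proteins that the liver of fish makes under estrogen. VEPA rose from -0.89 ± 0.44 in controls to 2.45 ± 1.04 (SD, n = 4 each), a difference of 3.34 (SE 0.46, adjusted p = 2.87e-05), VEPB by 3.01 (SE 0.49, adjusted p = 0.00031) and VEPG by 2.95 (SE 0.51, adjusted p = 0.000495). All 4 exposed arrays lay above each of the 4 controls in each of the 3 genes. VEPA was not above background on any of these control arrays, so its rise is at least 5.90-fold. At 0.1% sewage HSPA1A, the inducible HSP70 chaperone, rose by 1.30 (SE 0.25, adjusted p = 0.00158), at least 1.65-fold over controls in which it was not above background, and MHC2, a class II antigen-presenting gene, rose by 0.78 (SE 0.20, adjusted p = 0.046). Of 83 probes tested, 5 passed, all of them rises. The slope with concentration passed for VEPA (0.48 per step, adjusted p = 0.0014), VEPG (0.39), VEPB (0.39), cerebellin 4 (CBLN4, 0.42) and the iron carrier transferrin (TF, 0.30).

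Estrogen receptor alpha (ESR1) was 0.56 (SE 0.25) above control at 10% on day 4, CYP1A1 0.67 (SE 0.45), the metal-binding metallothionein MT1A 0.64 (SE 0.31) and HSPA1A 0.19 (SE 0.25), and none of these passed. The estrogen list had 5 measured members, of which VEPA, VEPB and VEPG rose, 0 fell and 2 did not pass. Adjusted over the list alone, 4 rose. The list passed (fry, adjusted p = 0.000708; adjusted p = 0.188 with an estimated correlation). The median of all tested probes stood 0.27 above control at 10%, so these values are relative to arrays centred on mostly undetected probes. Loess normalization turned the estrogen list and the 3 vitelline envelope genes to the other direction (VEPA -0.78), and it also returned -0.96 for a known rise of 3 put into the VEPA signal of control arrays. In fits without 1 array, the 3 vitelline envelope calls and that of HSPA1A held each time, while MHC2 lost its call in 15 of 27 and stood at -0.010 with the Cy5 signal alone. The 5 rises and 0 falls became 12 and 9 with loess, 5 and 2 with the Cy5 signal alone, and 3 and 1 with housekeeping centring. The 5 slopes became 1 without 10% replicate 2 and 12 without control replicate 3, and those of CBLN4 and TF lost their call in 7 of 27 fits each.

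After 8 days of exposure in year 1 the vitelline envelope genes were again the most changed at 10% sewage. VEPA stood at 3.28 ± 0.43 against -0.84 ± 0.20 in controls (SD, n = 4 each), a rise of 4.12 (SE 0.35, adjusted p = 7.54e-10) or at least 11.9-fold, since no control array had it above background. VEPG rose by 3.59 (SE 0.43, adjusted p = 1.04e-06) and VEPB by 3.32 (SE 0.25, adjusted p = 1.54e-10). CYP1A1, which oxidises aromatic pollutants and is switched on by the aryl hydrocarbon receptor, rose by 1.499 (SE 0.37, adjusted p = 0.031), with 2 of 4 exposed arrays above every control. At the lowest concentration, 0.05%, VEPB rose by 1.37 (SE 0.24, adjusted p = 0.000505) and VEPA by 1.31 (SE 0.33, adjusted p = 0.031, at least 1.71-fold), with all 5 exposed arrays above every control. Both comparisons used the same 4 control arrays. Between these concentrations VEPB was 0.35 at 0.1%, 0.58 at 0.7% and 0.81 at 2%, and none of the 3 passed.

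Of 85 probes tested on year 1 day 8, 6 comparisons passed, all rises. Slopes passed for VEPA (0.49 per step), VEPB (0.40), the sodium pump subunit ATP1A1C (0.15) and insulin-like growth factor 1 (IGF1, 0.10). ESR1 was 0.42 above control at 10% (SE 0.25), MT1A 0.55 (SE 0.31) and HSPA1A 0.03 (SE 0.24), and these did not pass. In the estrogen list 3 of 5 members rose and 2 did not pass, with the same count adjusted over the list alone (fry, adjusted p = 5.31e-09; adjusted p = 0.00468 with an estimated correlation). The xenobiotic list had 1 rise, CYP1A1, among 9 members, and did not pass as a list (adjusted p = 0.232). With loess VEPA, VEPB, VEPG and CYP1A1 turned to -1.39, -1.72, -1.13 and -2.02 at 10%, and the estrogen list to the other direction, and a rise of 3 put into the VEPA signal of control arrays came back as -1.12. Rises and falls were 1 and 5 with loess and 5 and 4 with housekeeping centring. The vitelline envelope calls at 10% and VEPB at 0.05% held in each of the 26 fits without 1 array, but loess turned VEPB at 0.05% to -1.38 and GFP centring ended its call. VEPA at 0.05% lost its call in 8 of 14 other settings and in 7 of the fits without 1 array, and CYP1A1 without control replicate 1, 2 or 4 or without 10% replicate 2 or 4 (adjusted p up to 0.195). No slope passed without 10% replicate 2, 3 or 4, and IGF1 lost its slope call in 18 fits.

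On the first day of exposure no probe passed at any concentration in either year. In year 1, limma called 0 of 70 probes (69 comparisons at an unadjusted p under 0.05), and in year 2 0 of 179 (118). The smallest p in year 1 belonged to CYP3A27 d195, a drug-metabolising P450, at 0.05% (1.07, SE 0.26, adjusted p = 0.0965), VEPA at 10% (0.86, SE 0.22, adjusted p = 0.0965, against controls without signal above background, so no fold is given) and SPARC, a matrix protein, at 0.1% (1.23, SE 0.32, adjusted p = 0.103). In year 2 they belonged to the growth factor gene IGF2 at 0.7% (-0.76, SE 0.17), its receptor IGF1R at 0.1% (-0.71, SE 0.16) and the thyroid hormone receptor THRA at 0.05% (-0.67, SE 0.16), each with an adjusted p of 0.0675. The slope with concentration did pass for some genes. In year 1 these were CYP1A1 (0.30 per step, adjusted p = 0.00877) and ESR1 (0.18, adjusted p = 0.00245). In year 2 ESR1 (0.15), CBLN4 (0.14), the muscle growth inhibitor GDF8 (0.13) and CAD2 (0.10) had rising slopes, and prolactin (PRL, -0.11) and gonadotropin-releasing hormone 2 (GNRH2, -0.10) falling ones.

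At 10% on year 1 day 1, CYP1A1 was 1.54 above control (SE 0.44, adjusted p = 0.114) and ESR1 0.78 (SE 0.22, adjusted p = 0.106, at least 1.16-fold, as no control array had it above background), and MT1A 0.58 (SE 0.37). The xenobiotic list passed there with 0 of 9 members passing singly and 4 rising when adjusted over the list alone (fry, adjusted p = 0.0317; adjusted p = 0.726 with an estimated correlation). Its largest members were CYP1A1, CYP2K5 (1.21), CYP2K4 (0.84) and CYP2M1 (0.72). The estrogen list passed likewise with 0 of 4 members passing singly and 2 rising over the list alone (adjusted p = 0.0141; adjusted p = 0.726 with an estimated correlation), VEPB at 0.68, VEPG at 0.68 and ESR1 at 0.78. The red cell genes HBA1 (-0.85) and HBB (-0.68) lay lower and HBG1 (0.78, not above background on any control) higher on the same arrays, without passing; adjusted over the red cell list alone, 1 of the 3 rose and 2 fell, and the list did not pass (adjusted p = 0.49). Control and exposed arrays came from different array series on this day, so series and exposure cannot be told apart, the median of all tested probes was 0.19 to 0.39 above control, and loess turned the xenobiotic list downward (adjusted p = 0.00914). The estrogen list lost its call with loess (adjusted p = 0.0776), and both lists lost theirs with housekeeping centring, centring on probes above background (0.279 for estrogen, 0.238 for xenobiotic) and GFP centring (0.158). Without 10% replicate 2 or 3 the slope of CYP1A1 lost its call and ESR1 was not tested. With loess the slope of CYP1A1 was -0.091. Without control replicate 2, 25 comparisons passed in year 1; without control replicate 3, 10% replicate 1 or 0.05% replicate 1 there were 1, 2 and 3. In year 2, at 5%, CYP1A1 was 0.29, ESR1 0.85 (adjusted p = 0.0946), MT1A 0.10, HSPA1A -0.08, the glucocorticoid receptor NR3C1 0.21, THRA -0.22, THRB -0.14 and vitellogenin (VTG) -0.09, none passing; ESR1 was not above background on any control there, THRA on any exposed array, and NR3C1 on either. Blank spots put the threshold at 11000 and 525.5 on control replicates 1 and 3, and at 992.2 on 5% replicate 1. Few probes could pass it on those arrays. The year 2 slopes fell from 6 to 0 without control replicate 1, an array with 3 probes above background. Without 1 array the slope of CBLN4 lost its call in 19 of 24 fits and those of GDF8, CAD2 and PRL in 16 each. PRL and GNRH2 changed sign with the Cy5 signal alone. Other scalings called probes on day 1: loess 36 in year 1 and 44 in year 2, the Cy5 signal alone 13 and 17, GFP centring 5 and 5, no background correction 79 in year 2 and centring on probes above background 3 there. In year 2, 1, 3 and 6 comparisons passed without replicate 4 at 0.1%, 0.05% and 0.7%.

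On day 4 of year 2, the rises at 5% sewage were in cerebellin 4, an iron carrier and an eggshell gene. CBLN4 rose by 1.48 (SE 0.31, adjusted p = 0.021), TF by 0.92 (SE 0.21, adjusted p = 0.0455) and VEPA by 0.92 (SE 0.21, adjusted p = 0.0429, from -0.64 ± 0.32 to 0.28 ± 0.32, SD, n = 4 each). GNRHR2, a receptor of gonadotropin-releasing hormone, fell by 0.93 at 5% (SE 0.19, adjusted p = 0.021) and by 1.07 at 2% (SE 0.19, adjusted p = 0.00734). VEPB was 1.15 above control (SE 0.30, adjusted p = 0.0733) and VEPG 0.91 (SE 0.29, adjusted p = 0.157), with all 4 exposed arrays of each above every control, but neither passed singly. Of 201 probes tested, 5 comparisons passed, 3 rises and 2 falls. In the slopes, where 7 rose and 3 fell, CBLN4 (0.30 per step), VEPB (0.25), VEPA (0.20), VEPG (0.18) and TF (0.16) were steepest upward, and GNRHR2 (-0.19), the retinol carrier RBP4 d227 (-0.17) and the proteasome subunit PSMC3 (-0.10) downward.

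At 5% on year 2 day 4, CYP1A1 (-0.23), ESR1 (0.16), MT1A (-0.15), HSPA1A (0.19), NR3C1 (-0.37), THRA (-0.17), THRB (0.11) and VTG (0.02) did not pass. The estrogen list held 1 rise among 9 members, or 3 rises and 1 fall adjusted over the list alone, and did not pass (adjusted p = 0.366). The slopes of VEPA, VEPB, CBLN4, TF and GNRHR2 held in each fit without 1 array, whereas that of VEPG lost its call in 16 of 24, RBP4 d227 in 13 and PSMC3 in 4. VEPA at 5% lost its call in 11 of 24, TF in 14, CBLN4 without control replicate 2 or 5% replicate 3 or 4, and GNRHR2 at 5% without control replicate 1 or 2 or 5% replicate 3 or 4. TF turned to -0.27 with loess, under which 5 comparisons were rises and 27 falls, against 1 and 2 with housekeeping centring and 2 and 3 with GFP centring, and the Cy5 signal alone called 0. Loess returned 0.29 for a rise of 3 put into VEPA on this day. The number of comparisons that passed ranged from 1 without control replicate 2, 5% replicate 3 or 5% replicate 4, through 3 without control replicate 3, replicate 1, 2 or 4 at 0.05%, replicate 3 at 0.1% or 0.7%, or replicate 1 at 5%, to 8 without 2% replicate 4 or 5% replicate 2 and 12 without 2% replicate 1.

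On day 8 of year 2, 8 probes fell and 2 rose at 5% sewage. 18S ribosomal RNA fell by 1.99 (SE 0.25, adjusted p = 1.58e-05), from 9.56 ± 0.33 to 7.57 ± 0.56 (SD, n = 4 each). The complement genes C4B (-1.39, SE 0.23, adjusted p = 0.000951), C1R d229 (-0.85, SE 0.18) and factor B (BF, -0.83, SE 0.16) fell, as did HSPCA, the HSP90 alpha chaperone (-1.05, SE 0.16, adjusted p = 0.000326), beta actin (ACTB, -0.94, SE 0.21), the glutamate-degrading enzyme GLUD1 (-0.87, SE 0.22) and GNRHR2 (-0.63, SE 0.15). VEPB rose by 0.83 (SE 0.21, adjusted p = 0.0459) and VEPA by 0.73 (SE 0.16, adjusted p = 0.0181), with all 4 exposed arrays of each above every control. At lower concentrations ACTB fell by 0.88 at 2%, the insulin receptor INSRA by 1.13 at 0.7%, and HSPA8, the constitutive HSP70, rose by 1.24 and the egg yolk precursor VTG by 0.76 at 0.1%. Of 203 probes, 14 comparisons passed, 4 rises and 10 falls, and 30 slopes, 6 rising and 24 falling. The steepest falls per step were 18S (-0.33), C4B (-0.20), ACTB (-0.20), HSPCA (-0.19) and GLUD1 (-0.17), and rises among them the heart myosin MYH6 (0.12), VEPA (0.12), VEPB (0.12) and the mitochondrial translocator BZRP (0.096).

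On year 2 day 8, 3 lists passed downward at 5%. The heat shock and protein turnover list had 1 fall (HSPCA) and 0 rises among 8 members, also adjusted over the list alone, and all 8 lay below control (fry, adjusted p = 1.1e-06; adjusted p = 0.439 with an estimated correlation), HSPA8 at -0.54, PSMC3 at -0.34 and the lysosomal protease CTSL at -0.33. The housekeeping list had 2 falls among 7, or 3 adjusted over the list alone (adjusted p = 0.00161; adjusted p = 0.726 with an estimated correlation), with the ribosomal proteins RPS6 at -0.68 and RPL23A at -0.29. The metabolism list had 1 fall among 17, or 5 over the list alone (adjusted p = 0.0391; adjusted p = 0.726 with an estimated correlation), with GLUD1, the glucose-releasing enzyme G6PC (-0.63), the branched-chain enzyme DBT (-0.61) and pyruvate kinase PKLR (-0.55). The immune list had 3 falls among 21, or 4 over the list alone, and did not pass in one direction (adjusted p = 0.136; 5.1e-07 for either direction), and the red cell genes HBA1 (-0.49) and HBB (-0.47) lay below all controls without passing. CYP1A1 (-0.05), ESR1 (-0.72, adjusted p = 0.0776), MT1A (0.53), HSPA1A (-0.30), NR3C1 (-0.29), THRA (-0.27) and THRB (0.13) did not pass at 5%, nor did VTG there (0.34).

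These falls depended on the scaling: centring on the housekeeping list turned the heat shock and metabolism lists upward and gave 421 rises and 2 falls, the Cy5 signal alone gave 4 rises and 2 falls, no background correction 8 and 6, GFP centring 0 and 4, and loess 11 and 6, with C4B at 0.84 under loess. All 3 lists lost their call with loess and with GFP centring, the housekeeping list also when centred on itself, and the metabolism list with no background correction (adjusted p = 0.459) and with centring on probes above background (0.147). The 6 rising and 24 falling slopes became 142 and 2 with housekeeping centring, 12 and 13 with loess, 0 and 29 with GFP centring, 8 and 10 with no background correction, 3 and 7 with the Cy5 signal alone and 10 and 10 with centring on probes above background. Loess returned -0.63 for a rise of 3 put into VEPA. The falls of 18S, C4B, HSPCA and BF held in each fit without 1 array. Without control replicate 3, 7 comparisons and 15 slopes passed, and without 5% replicate 2, 9 comparisons. That control ended the calls of C1R d229, ACTB and GNRHR2 at 5%, while control replicate 1 and 5% replicate 2 ended those of ACTB and GNRHR2, 5% replicate 3 or 4 that of GNRHR2, and 5% replicate 1 that of VEPA (adjusted p up to 0.0535). GLUD1 lost its call in 10 of 24 such fits, INSRA in 15 and VEPB in 16. VTG and HSPA8 at 0.1% and ACTB at 2% each lost theirs in 4. Loess turned HSPA8 at 0.1% to -0.18, and of the 12 other settings 2 more ended its call and 6 that of VTG at 0.1%. The rising slopes of MYH6, VEPB and BZRP lost their call in 16, 15 and 11, while the 5 falling slopes named held in each.

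**Figure D1:**
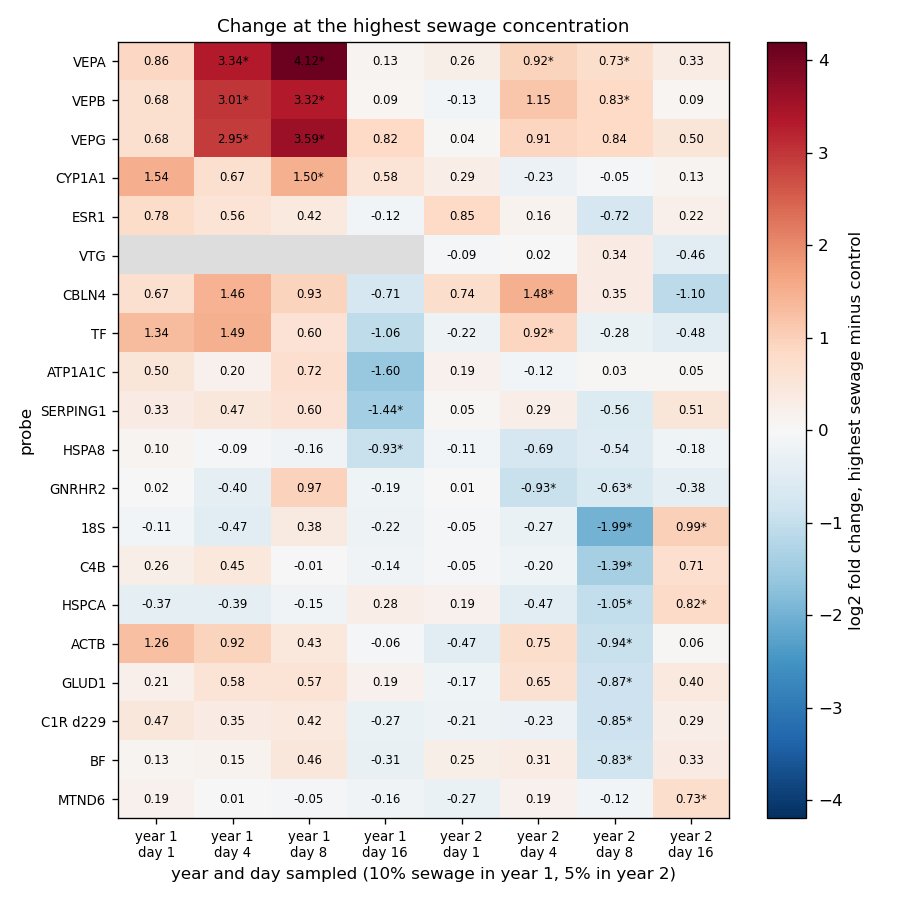
Log2 difference from control, by colour and printed value, at the highest concentration of each year and day (10% in year 1, 5% in year 2). The genes shown are a selection by hand from the named genes, not all of them. The vitelline envelope genes stand out on days 4 and 8 of year 1 (VEPA 3.34 and 4.12) and 18S on day 8 of year 2 (-1.99); loess normalization turns the former round.

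After 8 days in clean seawater the year 1 fish previously held at 10% no longer showed a vitelline envelope difference that passed: VEPA was 0.13 above control (SE 0.27), VEPB 0.09 (SE 0.35) and VEPG 0.82 (SE 0.47, adjusted p = 0.468). SERPING1, the inhibitor of the first complement component, fell by 1.44 at 10% (SE 0.28, adjusted p = 0.0102), from 5.93 ± 0.39 to 4.49 ± 0.34 (SD, n = 4 each), and HSPA8 by 0.93 (SE 0.19, adjusted p = 0.0102), though HSPA8 was above background on only 1 exposed and 2 control arrays. At 0.7% ATP1A1C fell by 1.93 (SE 0.45), SERPING1 by 1.22 (SE 0.28) and the lysosomal protease CTSD by 0.93 (SE 0.21), each with an adjusted p of 0.0221. Of 81 probes, 5 comparisons passed, all falls, and slopes fell for SERPING1 (-0.26 per step) and the glucose transporter SLC2A4 (-0.15). CYP1A1 was 0.58 (SE 0.33), ESR1 -0.12, MT1A 0.09, HSPA1A -0.74 and THRA -0.45 at 10%, none passing.

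The immune list fell on year 1 day 16 with 1 fall, SERPING1, among 8 members, also adjusted over the list alone (fry, adjusted p = 0.0391; adjusted p = 0.726 with an estimated correlation). TF was at -1.06, the prostaglandin enzyme PTGDS at -0.80 and galectin 9 (LGALS9) at -0.58, none passing singly. GFP centring turned this list upward and HSPA8 to 0.17. The red cell gene HBA1 lay 0.64 above control, but the red cell list did not pass (fry, adjusted p = 0.88). Of its 3 probes, 2 lay above control, and adjusted over the list alone 0 rose and 1 fell. The median of all tested probes stood at -0.36 for 0.7% and -0.11 for 10%. Controls lay in 3 array series and the 10% arrays in 1, and with series as a random block 2 comparisons passed; with loess there was 1 rise and 0 falls. The Cy5 signal alone and GFP centring each called 0, centring on probes above background 1 fall and housekeeping centring 26. The slope of SLC2A4 turned to 0.11 with GFP centring. The immune list lost its call with loess (adjusted p = 0.604), the Cy5 signal alone (0.461) and centring on probes above background (0.0868). The number was 2 without 0.7% replicate 1 or 2, 8 without 0.1% replicate 4, 9 without 0.7% replicate 3 and 10 without control replicate 3. The falls at 10% held in each such fit, whereas ATP1A1C, SERPING1 and CTSD at 0.7% each lost their call in 4 of 24, among them both 0.7% arrays just named.

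On year 2 day 16, 3 probes rose at 5%. 18S rose by 0.99 (SE 0.19, adjusted p = 0.0112), HSPCA by 0.82 (SE 0.17, adjusted p = 0.0221) and MTND6, a mitochondrially encoded subunit of respiratory complex I, by 0.73 (SE 0.16, adjusted p = 0.0242). At 2% 18S rose by 0.91 (SE 0.19, adjusted p = 0.0219), and at 0.7% STAR, which carries cholesterol to the start of steroid synthesis, rose by 1.80 (SE 0.31, adjusted p = 0.00409). RAG1, which recombines antigen receptor genes, fell by 0.55 at 0.05% (SE 0.12, adjusted p = 0.0242). Of 200 probes, 6 comparisons passed, 5 rises and 1 fall, and 11 slopes, 7 rising and 4 falling. Rising slopes were steepest for 18S (0.19 per step), C4B (0.18), HSPCA (0.13), the gonadotropin-releasing hormone receptor GNRHR (0.12) and MTND6 (0.11). Falling slopes were those of the stress hormone precursor POMC B (-0.11), INSRB (-0.089), VTG (-0.084) and the steroid enzyme CYP17A1 (-0.079).

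VEPA (0.33), VEPB (0.09), VEPG (0.50), CYP1A1 (0.13), ESR1 (0.22), MT1A (-0.56), HSPA1A (-0.18), NR3C1 (-0.03), THRA (0.10), THRB (-0.25) and VTG (-0.46, adjusted p = 0.094) did not pass at 5% on year 2 day 16. Loess turned 18S to -0.080, and rises and falls were 3 and 7 with loess, 1 and 9 with GFP centring, 5 and 15 with no background correction, 1 and 1 with housekeeping centring and 6 and 0 with centring on probes above background, while the Cy5 signal alone called 0. Rising and falling slopes, 7 and 4, became 1 and 10 with housekeeping centring, 2 and 10 with loess, 4 and 9 with no background correction and 9 and 0 with centring on probes above background, and GFP centring called 0. With the Cy5 signal alone the slopes of VTG (0.083, adjusted p = 0.0311), POMC B (0.068) and INSRB (0.010) changed sign. The 11 slopes became 2 without control replicate 4. Passing comparisons numbered 1 without control replicate 3, 2 without control replicate 2 and 10 without control replicate 4 or 0.05% replicate 1. 18S at 5% lost its call without either of control replicates 2 and 3, and STAR held in each of 24 fits. 18S at 2% and HSPCA at 5% lost theirs in 4 of 24, and MTND6 at 5% and RAG1 in 5. Among slopes, those of 18S and HSPCA held in each fit, while C4B, POMC B, INSRB and CYP17A1 lost their call in 15, GNRHR in 14, MTND6 in 6 and VTG in 4.

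Other lists did not pass in one direction at the highest concentration on any day tested. Across days, adjusted p ran from 0.187 to 0.955 for the red cell list, 0.198 to 0.913 for muscle and pancreas, 0.807 to 0.945 for metal and oxidative defence, 0.187 to 0.86 for hormone signalling, 0.198 to 0.913 for cell cycle and damage, and 0.125 to 0.994 for transport. On the days not counted as passing above, the estrogen list had an adjusted p of 0.79 on year 1 day 16 and 0.353, 0.366, 0.198 and 0.419 on days 1, 4, 8 and 16 of year 2, and the xenobiotic list 0.473, 0.232 and 0.955 on days 4, 8 and 16 of year 1 and 0.322, 0.955, 0.569 and 0.741 on days 1, 4, 8 and 16 of year 2. On their other days the immune list ran from 0.11 to 0.807, heat shock from 0.174 to 0.807, housekeeping from 0.322 to 0.945 and metabolism from 0.198 to 0.86. Tested for changes in either direction, the hormone list passed on days 1, 8 and 16 of year 2 (adjusted p = 0.0254, 0.00452 and 0.0254), the immune list also on day 16 (0.000477) and the metabolism list on day 4 (0.0259). The leukocyte list had 1 probe, MHC2, and was not tested. For cell cycle and damage on year 2 day 8, the median (0.05) and mean (0.02) lay above 0 while fry pointed down. In all, 8 of 81 list tests passed, and 4 without either control replicate 1 or 10% replicate 2 of year 1 day 1.

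The change from day 8 to day 16 at the highest concentration was tested directly as a difference of differences from control. In year 1, falls were seen in VEPA (-3.99, SE 0.40, adjusted p = 7.83e-16, from a day 8 rise of at least 11.9-fold over controls in which it was not above background), VEPB (-3.23, SE 0.50, adjusted p = 9.2e-08), ATP1A1C (-2.31, SE 0.35, adjusted p = 8.82e-08) and CCK1, a cholecystokinin gene (-1.53, SE 0.29, adjusted p = 1.94e-05). In year 2 18S rose by 2.97 (SE 0.51, adjusted p = 2.51e-06), from -1.99 on day 8 to 0.99 on day 16. Of 279 tests, 22 passed: in year 1 11 were lower and 1 higher on day 16, and in year 2 9 were higher and 1 lower. For VEPA and VEPB, year 1 controls read higher on day 16 than on day 8. In mean background-subtracted Cy5, VEPA went from 36.39 to 133.5 in controls and from 2125 to 162.3 at 10%. VEPB went from 319.4 to 568.6 in controls and from 3862 to 608.7 at 10%. The 10% arrays thus fell, and higher controls may add to the difference. Days differed in array series in year 1. With series as a fixed term VEPA was -4.10, VEPB -2.96 and ATP1A1C -2.19, and 9 of the 11 lower probes still passed. Loess turned VEPA (1.28), VEPB (0.89) and CCK1 (0.35) to the other direction, and centring on the housekeeping list gave 3 higher and 35 lower, no background correction 8 and 22, and centring on probes above background 14 and 5. The Cy5 signal alone left 11 passing and GFP centring 2.

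The response to 2% sewage, the highest concentration shared by both years, was compared between years for each day. limma called 0 of 319 tests, with 58 at an unadjusted p under 0.05. The smallest adjusted p, 0.062, was shared by 7 tests. On day 4 these were SOX9, a transcription factor (1.22, SE 0.33), the glutamine synthetase GLUL3 (-0.95, SE 0.27), GNRHR2 (-1.36, SE 0.40) and CTSL (-1.43, SE 0.43), on day 1 SPARC (-1.09, SE 0.31), and on day 16 C4B (1.44, SE 0.44) and IGF2 (-1.14, SE 0.35). Years differed in array series throughout, so year and series cannot be told apart. This fit had no series term, and on year 1 day 4 it set the 2% arrays, all of 1 series, against controls of 2. The number of tests that passed was 12 with loess, 18 with housekeeping centring, 9 with no background correction, 4 with the Cy5 signal alone and 63 with GFP centring, and up to 12 without 1 array (the day 4 control replicate 5 of year 1). The 10% response of year 1 and the 5% response of year 2 were not tested against each other, as the concentrations differ.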

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

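The tests on unspecific Cy5 signal, on the year difference in response, on a shift with signal strength, on control arrays, on array series as a fixed term and on the end of exposure were chosen only after the result was seen, whereas the splits of the arrays were set before. The check for outlying arrays took in 129 checks, each of 1 group in 1 measure, and by chance it marks about 1 in 20 of them; 6 were marked. In 5 of them the number of probes above background stood apart. On day 1 of year 1 at 0.05%, replicate 3 had 70 (others 52 to 53). On day 1 of year 2, replicate 3 at 0.1% had 76 (170 to 175) and replicate 1 at 5% had 25 (130 to 141). The thresholds set by the blank spots of these 2 arrays, 303 and 992.2, were the highest of their groups. Control replicate 3 on year 2 day 8 had 197 (201 to 201), and replicate 1 at 0.05% on year 2 day 16 had 169 (199 to 200). For VTG at 0.1% on year 2 day 8, replicate 3 lay at 0.03892 against -1.03 to -0.8831 in the other arrays, and without it the VTG call there was lost.

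Between day 8 and day 16 at the highest concentration, 22 probes differed in their distance from control, of which 21 are given. In year 1 the differences were -3.993 for VEPA, -3.229 for VEPB, -2.769 for VEPG, -2.314 for ATP1A1C, -2.043 for SERPING1, -1.564 for ACTA1, -1.548 for APOE, -1.53 for CCK1, -1.518 for SOX9, -1.202 for CTSD, -1.069 for IGF1 and 1.453 for HBA1. In year 2 they were 2.974 for 18S, 2.097 for C4B, 1.865 for HSPCA, 1.221 for STAR, 1.198 for CYP3A27 d196, 1.149 for C1R d229, 1.008 for SOXLZ, 0.8847 for DBT and -1.031 for MYH6. Loess turned VEPA, VEPB and CCK1 to the other direction.

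The genomic actin probe served as a control and not as a gene. On year 1 day 4 it was above background on 18 of 19 exposed arrays (94.74%) and 4 of 8 control arrays (50%). This was the 1 flag among the 3 genomic or intron control probes, compared on 8 occasions, so chance is not excluded. The arrays of that day lay in different array series and were pooled here. For the same probe, the shares were 50% and 25% on year 1 day 1, and 95% and 50% on year 2 day 1. They went the other way on year 1 day 8 (90.91% and 100%) and day 16 (80% and 100%). On days 4, 8 and 16 of year 2 both were 100%.

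The first pattern weighed was that VEPA and VEPB rose less at the highest concentration on day 8 in year 2 (0.73 and 0.83) than in year 1 (4.12 and 3.32, the former against controls without signal above background). A median of 90.91% of 22 probes for genes of other tissues lay above background on arrays of year 2 day 8. On those of year 1 day 8 it was 0. Unspecific Cy5 signal that compresses ratios could thus account for part of the pattern. Mean background-subtracted Cy5 of VEPA went from 36.39 in controls to 2125 at 10% in year 1. In year 2 it went from 511.1 to 762.4 at 5%. VEPB went from 319.4 to 3862 in year 1 and from 762.6 to 1100 in year 2. Added signal would not lower the exposed means, so these values argue against it as the whole account. This assumes 1 Cy5 scale in both years, which is not known. A difference in the response of the fish stays open: the smaller adjusted p of the year difference at 2% was 0.5747, and the highest concentrations, 10% and 5%, differed. Year and array series cannot be told apart.

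The second pattern was the fall of 18S, C4B, HSPCA, ACTB and 4 other probes at 5% on day 8 of year 2. With the Cy5 signal quantile normalized, 68.51% of the median fall was kept (-0.9086 to -0.6225), with 2 of 8 still called, so an array-wide shift with signal strength may be part of it and was not excluded. Controls lay 0.3326 above the lower concentrations, 60.94% of the step of 0.5458 from these to 5%. The 8 probes were picked for a fall against these same controls with median centring. That choice alone can place controls above the lower concentrations, and can shrink the fall under another scaling. Whether control arrays stand apart is therefore left open. An effect of sewage also stays open, and the labels give nothing else that would separate these.

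The third pattern was the set of 11 probes lower after 8 clean days than after 8 days at 10% in year 1. With array series as a fixed term 81.82% of them, 9 of 11, were still called, while APOE went from -1.55 to -1.09 (adjusted p = 0.284) and CTSD from -1.20 to -0.89 (adjusted p = 0.13); the smaller difference and the added term ended both calls. Series could therefore account for part of these. With the series term VEPA stayed at -4.10, VEPB at -2.96 and VEPG at -2.85. For VEPA and VEPB, 4 of 4 arrays of day 16 at 10% lay below every 10% array of day 8. These probes were picked for that difference and the 10% arrays of the 2 days lay in different series, so this array comparison does not favour the end of exposure. The recovery differences were taken from controls of the same day, so an effect of day or age shared by both groups drops out of them. No group was held in sewage until day 16, so a change with time in exposed fish alone and the end of exposure cannot be told apart.

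For each count, 100 splits of the same arrays into groups of the same sizes were drawn, the real one included. They kept array series only on year 1 day 4, so elsewhere they speak of chance and not of series, and on days 1 and 16 of year 1, where series is bound to group, no statement on chance is drawn from them. A real count of 0 is reached by every split, which decides nothing: this holds for the concentrations against control on day 1 of both years (100 of 100 splits; highest other 21 in year 1 and 2 in year 2) and for the year difference at 2% (100; highest other 3). The split with 21 could reflect a structure among those arrays, which was not examined. Few splits reached the real count for the concentrations on year 1 day 4, with 1 split as large (real 5, highest other 3), the real one itself. On year 1 day 8 there were 2 (6, 8), and 1 each on year 2 day 4 (5, 1), day 8 (14, 7) and day 16 (6, 3). On year 1 day 16, 2 splits were as large (5, 12). For slopes 3 splits were as large on year 1 day 4 (real 5, highest other 20) and 1 on day 8 (4, 1). On each day of year 2 there was 1 (6, 10, 30 and 11, highest other 1 each). On year 1 days 1 and 16, 2 splits each were as large (2, 2). The split with 20 slopes on year 1 day 4 was not examined either. With 100 splits per count and no adjustment over the counts, a small share does not exclude chance. The 6 slopes of year 2 day 1 also fell to 0 without control replicate 1. For the recovery difference 1 split was as large (22, 6), and for the list tests 1 (8, 4); both counts include year 1 days on which series is bound to group.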

How the results depend on the processing

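The tests chosen only after the result was seen were centring on probes above background, centring on the GFP spots, leaving out the 3 arrays of fewest detected probes, the first filter of the difference tests, array series as a fixed term for recovery, the list tests under other settings and the known rise put into control arrays. The other alternatives were set before the data were examined. Signal over background was lower in year 1, where a median of 65 of 203 probes lay above background on an array, against 191 in year 2. The rises of VEPA, VEPB and VEPG at 10% on days 4 and 8 of year 1 kept their direction and their side of the threshold under each alternative that gave them a value, apart from loess. Loess turned them round by its construction: a rise of 3 on the log2 scale put into the Cy5 signal of control arrays came back as 2.99 with median centring, but as -0.96, -1.01 and -0.72 for VEPA, VEPB and VEPG on year 1 day 4 with loess. On year 1 day 8 it came back as -1.12, -1.80 and -1.03, on year 2 day 4 as 0.29, 0.25 and 2.49, and on year 2 day 8 as -0.63, -0.52 and 0.89. The log ratio rose with spot intensity across probes, with a median slope of 1.37 in year 1 and 0.77 in year 2, and loess removed that slope together with the bright probes' change. Among named genes outside the fits without 1 array, 1672 values kept direction and side of the threshold, 304 became weaker, 49 stronger and 42 reversed. In fits without 1 array, 3738 stayed, 435 became weaker and 83 stronger, and of 91 named calls 36 held in each such fit. Only 4 of the 91 were kept in every other setting. Counts stayed within 1.5 times of the reported count in 145 alternatives and moved beyond it in 124. Centring on the housekeeping list moved year 2 day 8 most, by 0.67 at 2%. At 5% on that day 18S and ACTB, which are on that list, fell, and only 1 of the 7 list members lay above control. Whether 18S and ACTB caused the move was not tested. Leaving out all but the largest series on year 1 day 4 leaves out the 10% arrays. The fit over all groups had no array series term and 1 estimate of the spread. For the other changes below the cause was not tested. Replicate numbers were given by the labels, yet same-numbered arrays did not deviate together: their mean correlation was -0.0047 to 0.0711 per year and day, and the lowest pair reached -0.551, so the block is listed only here. A random series block was not run on year 1 day 1, where series and exposure cannot be told apart, and the largest series was not run on year 1 day 1 or year 1 day 16, which held 0 and 1 controls in it. The submitters' processed values gave no named genes or lists, since their entries carry no gene names, and the gene lists could not use the series settings.

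GFP centring, which took off Cy5 signal alone, left Cy3 differences between arrays in the ratios. Relative to median centring of all probes, the median of tested probes moved by more than 0.1 on the log2 scale in 29 of 40 contrasts with GFP centring, at most by 1.105, and in 30 with the housekeeping list, at most by 0.67. It moved in 19 with probes above background, in 11 with Cy5 alone, in 12 with loess and in 1 without background correction. Counts that moved beyond 1.5 times, or whose share of rises moved by over 10 percentage points, follow as probes called, with the direction given where that share moved. With loess within each array, the concentration comparisons called 36 on year 1 day 1, 21 (12 higher, 9 lower) on day 4, 6 (1 higher, 5 lower) on day 8, 1 (1 higher, 0 lower) on day 16, 44 on year 2 day 1, 32 (5 higher, 27 lower) on day 4, 17 (11 higher, 6 lower) on day 8 and 10 (3 higher, 7 lower) on day 16. The trends called 1 on year 1 day 1, 1 on day 4, 4 (1 higher, 3 lower) on day 8, 0 on day 16, 22 (11 higher, 11 lower) on year 2 day 1, 31 (9 higher, 22 lower) on day 4, 25 (12 higher, 13 lower) on day 8 and 12 (2 higher, 10 lower) on day 16. Year differences numbered 12 and 4 list tests passed. Under the Cy5 signal alone, quantile normalized, the concentration comparisons called 13 on year 1 day 1, 7 (5 higher, 2 lower) on day 4, 0 on day 16, 17 on year 2 day 1, 0 on day 4, 6 (4 higher, 2 lower) on day 8 and 0 on day 16. Its trend counts were 6 (4 higher, 2 lower) on year 1 day 4, 2 on day 8, 1 on day 16, 20 on year 2 day 1, 7 (4 higher, 3 lower) on day 4 and 10 on day 8. For the year difference it called 4, the recovery difference called 11 and 13 list tests passed. With centring on the housekeeping list, the concentration comparisons called 4 (3 higher, 1 lower) on year 1 day 4, 9 (5 higher, 4 lower) on day 8, 26 on day 16, 3 (1 higher, 2 lower) on year 2 day 4, 423 (421 higher, 2 lower) on day 8 and 2 (1 higher, 1 lower) on day 16. Trends gave 0 on year 1 day 1, 1 on day 8, 10 on day 16, 0 on year 2 day 1, 8 (7 higher, 1 lower) on day 4, 144 (142 higher, 2 lower) on day 8 and 11 (1 higher, 10 lower) on day 16. The year difference called 18, the recovery difference called 38 (3 higher, 35 lower) and 14 list tests passed. Under no background correction, the concentration comparisons called 10 on year 1 day 16, 79 on year 2 day 1, 23 on day 4, 14 (8 higher, 6 lower) on day 8 and 20 (5 higher, 15 lower) on day 16. Trend counts were 29 (7 higher, 22 lower) on year 2 day 1, 16 on day 4, 18 (8 higher, 10 lower) on day 8 and 13 (4 higher, 9 lower) on day 16. Year differences numbered 9 and the recovery difference called 30 (8 higher, 22 lower). With centring on probes above background, the concentration comparisons called 1 on year 1 day 16, 3 on year 2 day 1 and 6 (6 higher, 0 lower) on day 16. The trends called 2 (1 higher, 1 lower) on year 1 day 1, 3 on day 4, 2 on day 8, 1 on day 16, 2 (1 higher, 1 lower) on year 2 day 1, 12 (7 higher, 5 lower) on day 4, 20 (10 higher, 10 lower) on day 8 and 9 (9 higher, 0 lower) on day 16. The recovery difference called 19 (14 higher, 5 lower) and 4 list tests passed. Under centring on the GFP spots, the concentration comparisons called 5 on year 1 day 1, 3 on day 8, 0 on day 16, 5 on year 2 day 1, 5 (2 higher, 3 lower) on day 4, 4 (0 higher, 4 lower) on day 8 and 10 (1 higher, 9 lower) on day 16. Its trend counts were 1 on year 1 day 1, 2 on day 8, 0 on day 16, 4 (4 higher, 0 lower) on year 2 day 1, 5 on day 4, 29 (0 higher, 29 lower) on day 8 and 0 on day 16. For the year difference it called 63, the recovery difference called 2 and 2 list tests passed. With no filter on dim probes, the trends called 3 on year 1 day 4. With no filter on dim probes, 5 list tests passed. Under the stricter filter on dim probes, the trends called 1 on year 1 day 1 and 1 on year 2 day 1. With the submitters' processed values, the concentration comparisons called 0 on year 1 day 16, 0 on year 2 day 4, 1 on day 8 and 0 on day 16. Trends gave 1 on year 1 day 1, 0 on day 8, 0 on day 16, 1 on year 2 day 1, 4 on day 4, 9 on day 8 and 0 on day 16. The year difference called 2 and the recovery difference called 12. Under array series as a random block, the concentration comparisons called 2 on year 1 day 16. Trend counts were 1 on year 1 day 16 and 17 on year 2 day 16. With no array series term, the concentration comparisons called 10 on year 1 day 4. The trends called 3 on year 1 day 4. Under only the largest array series, the concentration comparisons called 1 on year 1 day 4. Its trend counts were 0 on year 1 day 4. With the replicate block, the concentration comparisons called 8 on year 1 day 16. Trends gave 3 on year 1 day 4 and 5 on year 2 day 16. Year differences numbered 4. Under 1 fit over all 48 groups, the concentration comparisons called 42 on year 1 day 1, 76 on day 4, 15 on day 8, 18 on day 16, 4 on year 2 day 1, 0 on day 4, 5 on day 8 and 2 on day 16. Trend counts were 9 on year 1 day 1, 17 on day 4, 15 on day 16, 3 on year 2 day 4, 9 on day 8 and 6 on day 16. With adjustment within each contrast, the concentration comparisons called 5 on year 1 day 1, 8 on day 4, 17 on day 16, 3 on year 2 day 1 and 10 on day 4. For the year difference it called 7. Under the concentration in percent, the trends called 5 on year 1 day 1, 3 on day 4, 6 on day 16, 0 on year 2 day 1, 3 on day 4 and 1 on day 16. With the 3 arrays of fewest detected probes left out, the trends called 0 on year 2 day 1. Camera passed 3 list tests with a preset correlation and 1 with an estimated correlation, and fry's test for changes in either direction passed 10. The recovery difference called 21 with the first filter, which kept probes detected in both years. 

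Named values that changed sign, on the log2 scale, were these. With loess within each array, CYP3A27 d195 was -1.57 and CYP2M1 was -1.40 at 10% on year 1 day 1 and VEPA was -0.78, VEPB was -1.33 and VEPG was -0.996 at 10% on year 1 day 4. There, VEPB was -1.38 at 0.05% on year 1 day 8 and VEPA was -1.39, VEPG was -1.13, VEPB was -1.72 and CYP1A1 was -2.02 at 10% on year 1 day 8. And TF was -0.27 and HSPA1A was -1.34 at 5% on year 2 day 4 and HSPA8 was -0.18 at 0.1% on year 2 day 8. Also, C4B was 0.84 at 5% on year 2 day 8 and 18S was -0.080 and CYP1A1 was -1.22 at 5% on year 2 day 16. Slopes were CYP1A1 -0.091 on year 1 day 1 and VEPA -0.089, VEPG -0.13, VEPB -0.082 and TF -0.076 on year 1 day 4. Slopes were VEPA -0.25 and VEPB -0.24 on year 1 day 8 and TF -0.055 on year 2 day 4. Slopes were C4B 0.091 on year 2 day 8 and C4B -0.094 on year 2 day 16. Recovery differences were VEPA 1.28, VEPB 0.89 and CCK1 0.35 in year 1. With the Cy5 signal alone, quantile normalized, MHC2 was -0.010 at 0.1% on year 1 day 4. Slopes were IGF1 -0.044 on year 1 day 8 and PRL 0.13 and GNRH2 0.015 on year 2 day 1. Slopes were POMC B 0.068, INSRB 0.010 and VTG 0.083 on year 2 day 16. With centring on the housekeeping list, CYP1A1 was 0.51 at 5% on year 2 day 8. With only the largest array series, slopes were VEPG -0.035 and VEPB -0.044 on year 1 day 4. With centring on the GFP spots, HSPA8 was 0.17 at 10% on year 1 day 16. Slopes were SLC2A4 0.11 on year 1 day 16 and BZRP -0.0037 on year 2 day 8.

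Leaving out 1 array at a time gave these ranges. The count of 0 for year 1 day 1 concentrations ranged from 0 to 25, with 1 without control replicate 3, 2 without 10% replicate 1, 3 without 0.05% replicate 1 and 25 without control replicate 2. A count of 5 for year 1 day 4 concentrations ranged from 4 to 7. The reported count of 6 for year 1 day 8 concentrations ranged from 4 to 7. Likewise, the 5 for year 1 day 16 concentrations ranged from 2 to 10, with 2 without 0.7% replicate 1 or 0.7% replicate 2, 8 without 0.1% replicate 4, 9 without 0.7% replicate 3 and 10 without control replicate 3. The count of 0 for year 2 day 1 concentrations ranged from 0 to 6, with 1 without 0.1% replicate 4, 3 without 0.05% replicate 4 and 6 without 0.7% replicate 4. A count of 5 for year 2 day 4 concentrations ranged from 1 to 12, with 1 without control replicate 2, 5% replicate 3 or 5% replicate 4, 3 without control replicate 3, 0.05% replicate 1, 0.05% replicate 2, 0.05% replicate 4, 0.1% replicate 3, 0.7% replicate 3 or 5% replicate 1, 8 without 2% replicate 4 or 5% replicate 2 and 12 without 2% replicate 1. The reported count of 14 for year 2 day 8 concentrations ranged from 7 to 18, with 7 without control replicate 3 and 9 without 5% replicate 2. Likewise, the 6 for year 2 day 16 concentrations ranged from 1 to 10, with 1 without control replicate 3, 2 without control replicate 2 and 10 without control replicate 4 or 0.05% replicate 1. The count of 2 for the year 1 day 1 trend ranged from 0 to 3, with 0 without 10% replicate 2 or 10% replicate 3. A count of 5 for the year 1 day 4 trend ranged from 1 to 12, with 1 without 10% replicate 2, 3 without control replicate 2, control replicate 4, 10% replicate 4 or 2% replicate 3, 9 without control replicate 5 and 12 without control replicate 3. The reported count of 4 for the year 1 day 8 trend ranged from 0 to 5, with 0 without 10% replicate 2, 10% replicate 3 or 10% replicate 4 and 1 without 10% replicate 1. Likewise, the 2 for the year 1 day 16 trend ranged from 1 to 5, with 1 without control replicate 2, 10% replicate 3 or 10% replicate 4, 4 without control replicate 4 or 2% replicate 3 and 5 without control replicate 3. The count of 6 for the year 2 day 1 trend ranged from 0 to 6, with 0 without control replicate 1, 1 without 5% replicate 1 or 5% replicate 2, 2 without control replicate 2, control replicate 3, 0.05% replicate 1, 0.05% replicate 2, 0.05% replicate 4, 0.1% replicate 1, 0.1% replicate 2, 0.7% replicate 2 or 2% replicate 3 and 3 without 0.05% replicate 3, 2% replicate 2, 5% replicate 3 or 5% replicate 4. A count of 10 for the year 2 day 4 trend ranged from 6 to 12, with 6 without control replicate 1. The reported count of 30 for the year 2 day 8 trend ranged from 15 to 28, with 15 without control replicate 3, 17 without 5% replicate 1 and 19 without 0.1% replicate 4, 0.7% replicate 4 or 2% replicate 3. Likewise, the 11 for the year 2 day 16 trend ranged from 2 to 16, with 2 without control replicate 4, 3 without control replicate 3, 0.05% replicate 2 or 2% replicate 3, 4 without 0.05% replicate 3, 0.1% replicate 3, 0.7% replicate 2, 2% replicate 1 or 5% replicate 4, 5 without 0.05% replicate 4, 2% replicate 4, 5% replicate 1 or 5% replicate 2 and 6 without control replicate 2, 2% replicate 2 or 5% replicate 3. The count of 0 for the year difference ranged from 0 to 12, with 2 without year 2 day 1 2% replicate 4, 4 without year 1 day 4 control replicate 6, year 1 day 4 control replicate 7, year 1 day 4 control replicate 8, year 1 day 8 2% replicate 4, year 1 day 16 control replicate 4, year 1 day 16 2% replicate 3, year 2 day 8 control replicate 3 or year 2 day 16 control replicate 3, 5 without year 1 day 4 2% replicate 2 or year 1 day 16 2% replicate 4, 6 without year 1 day 16 control replicate 2, 7 without year 1 day 1 control replicate 2 or year 2 day 16 control replicate 1, 8 without year 1 day 4 control replicate 3, 11 without year 1 day 1 control replicate 3 and 12 without year 1 day 4 control replicate 5. A count of 22 for the recovery difference ranged from 16 to 27. The reported count of 8 for the list tests ranged from 4 to 9, with 4 without year 1 day 1 control replicate 1 or year 1 day 1 10% replicate 2.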

Other observations

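All tests in this part on single arrays, spots, control probes and replicate numbers were chosen only after the result was seen; the recovery difference was planned. Among probes with a recovery difference that passed at 5% sewage in year 2, C4B went from -1.39 to 0.71 (difference 2.10, adjusted p = 0.00012), HSPCA, an HSP90 chaperone, from -1.05 to 0.82 (1.87, adjusted p = 3.2e-05) and C1R d229, which starts the classical complement pathway, from -0.85 to 0.29 (1.15, adjusted p = 0.0243). STAR went from -0.37 to 0.85. On day 16 C4B, C1R d229 and STAR did not pass at 5%, loess put C4B at 0.84 on day 8, and housekeeping centring gave 3 higher and 35 lower recovery differences over both years. In year 1 at 10%, SERPING1 went from 0.60 to -1.44 (-2.04, adjusted p = 9.45e-05), the sodium pump subunit ATP1A1C from 0.72 to -1.60, IGF1 from 0.65 to -0.42, and the hemoglobin gene HBA1 from -0.81 to 0.64 (1.45, adjusted p = 0.0127). Of these 8 genes, STAR, ATP1A1C, IGF1 and HBA1 did not pass at the highest concentration on either day alone. HBB and HBG1, the other red cell probes, had no recovery difference that passed in year 1.

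The arrays with the fewest probes above background were year 1 day 1 at 2% replicate 1 (7), year 2 day 1 control replicate 1 (3) and year 2 day 1 at 5% replicate 1 (25), and without the 3 the slopes called on year 2 day 1 went from 6 to 0. Their blank spots set thresholds of 4864, 11000 and 992.2, in that order, while their median Cy5 intensities were 247.5, 527.6 and 640.9. On year 2 day 1 control replicate 2 the threshold was 150.6 and the median 551.7. The low counts thus came with high blank thresholds, not with a dim array as a whole. The 2 spots of CYP1A2 d194 differed by 2.09 in log2 Cy3 signal (4.26-fold) and those of CYP1A2 d54 by 2.05 (4.15-fold), ahead of PSMB9 at 1.31 and VEPB at 0.36. Whether spots of the 2 CYP1A2 probes are exchanged is not known; if so, the averaged value of each mixes 2 probes, and both belong to the xenobiotic list that was tested. The median share of 22 probes for genes of other tissues above background was 61.36%, 86.36%, 90.91% and 90.91% on days 1, 4, 8 and 16 of year 2 and 0 on each day of year 1. A probe for an IL1B intron was above background on 18 of 20 exposed and 4 of 4 control arrays on year 2 day 8 and on 0 arrays of year 1. The other intron probe, of GH1, was above background on 20 of 20 and 4 of 4 on year 2 day 8. In year 1 it was so on 22 of 22 and 4 of 4 on day 8, and on 6 of 20 and 0 of 4 on day 1. Signal at intron probes was therefore not confined to year 2. The highest correlation of log2 Cy5 signal between 2 arrays was 0.9784 and the lowest of log ratios 0.6789.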
